A study of Mus musculus with 6 samples.

How the data were processed

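Total RNA of whole mouse uterus from 3 control samples and 3 Ihh-ablated samples was labelled as biotinylated cRNA and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels. Groups and replicate numbers were taken from the sample titles and genotypes. The source field of the labels names a Smoothened model in both groups, which conflicts with those titles, and it was not used for grouping. The deposited file gives the authors' processed intensity per probe set on a linear scale for each of the 6 arrays. The software that summarised the probes, the background correction and the normalization between arrays are not given in the sources used here. No detection calls were used, so a dim probe set has no stated background. Signal that the authors' processing added to or removed from dim probe sets would change their fold changes most.

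Of 45101 probe sets, 64 control probe sets were left out. Among the other 45037, the platform annotation gave 1 gene symbol for 34945, several for 932 and none for 9160, which stayed unnamed, and genes were named only from probe sets with 1 symbol. By Entrez identifier 34754 of those matched the mouse gene table of assembly GRCm38.p6, and 0 symbols changed. Intensities under 16 were set to 16 (1821 values) before log2 was taken. Array medians of the log2 values differed by at most 0.231, below the limit of 0.3 set for renormalization, so the authors' normalization was kept. The median log2 difference of all probe sets was -0.04, and changes are not relative to it. Probe sets in the lowest 25% by mean log2 over the 6 arrays (under 6.16) were left out, which left 33777.

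Genotypes were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend (4 residual and 5.25 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all tested probe sets. Differences are Ihh-ablated minus control, means and SDs are of linear intensities, and folds and SEs come from the log2 model. A gene was represented by its brightest probe set with 1 symbol. Fixed lists, 43 of them, were tested by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move, on balance, 1 way without comparing them with other genes. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named Ihh, Pgr, Esr1, Nr2f2, Ptch1, Gli1 and Hhip, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and up to 4 members of lowest p per list, with other called members as a short enumeration. Pancreas markers, the adipocyte covariate and the fit without 2 arrays were added after seeing the data. In simulated data of 33777 probe sets the fit recovered 96 of 100 probe sets changed 2-fold and 100 of 100 changed 4-fold, with 14 false calls among 210. The simulated noise was independent between probe sets, without an outlying array or other tissue, so recovery on these arrays may be lower. With the mitotic list lowered, camera called it and 1 other list.

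Alternatives changed the normalization, the floor, the filter, the variance model, array weights, the replicate block, the arrays included, the threshold, the probe set that stands for a gene and the set test. Scan dates were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.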

Results

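Uterine RNA was profiled from 3 control samples carrying floxed Indian hedgehog (Ihh) alleles without ablation and from 3 samples in which Ihh was ablated by a Cre recombinase expressed from the progesterone receptor locus. Ihh encodes a secreted ligand of the Hedgehog pathway that the uterine epithelium makes and the stroma receives. All 6 samples were taken on day -1 of an artificial decidual response, a hormone regimen followed by a mechanical stimulus that makes the endometrial stroma differentiate as in pregnancy. Each sample was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, and the file holds 1 intensity per probe set and array. Median intensities lay between 121.4 and 142.5, the highest in control replicate 2. The lowest correlation between arrays (Pearson, across probe sets of an array, which are not independent replicates) was 0.951, between control replicate 2 and Ihh-ablated replicate 3. Control replicate 2 also had the highest lower quartile of intensity (79.8, against 66.6 to 72.1). Its spike-in controls lay 0.33 log2 above their 6-array mean, against -0.17 to 0.07 in the other arrays. Whether this moved dim probe sets was not tested. The number of arrays, 3 per group, limits the precision. The labels do not say whether each sample came from a separate mouse, so the p-values measure the spread between these samples, which may be technical. The source field of the labels names another mouse model, an activated Smoothened allele, whereas titles, genotypes and the design text all give the Ihh genotypes used here.

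The comparison of both genotypes asks which uterine transcripts differ without Ihh on this day. The Cre at the Pgr locus goes with the ablation, so its own effect cannot be told apart from that of Ihh loss. The single Ihh probe set read 155.5 ± 13.3 in control and 116.7 ± 21.5 in Ihh-ablated uteri (mean intensity ± SD, n = 3 each), a log2 difference of -0.43 with an adjusted p of 0.164, so the fall did not pass the test although the groups did not overlap. Without Ihh-ablated replicate 2 the difference was -0.27 (adjusted p = 0.417). Individual arrays read 163.9, 162.3 and 140.2 in control and 121.4, 93.3 and 135.4 in Ihh-ablated uteri. This probe set lay at the 52.1 percentile of all probe sets. The labels do not say which part of the gene was removed, so it may lie outside the deleted part and then checks nothing. Gli1, the transcription factor whose own transcription reports Hedgehog signalling, fell from 419.0 ± 84.7 to 72.0 ± 6.3 (5.76-fold lower, log2 -2.53, SE 0.16, adjusted p = 0.000492). Ptch1, the Hedgehog receptor and a direct target, fell from 1302 ± 269 to 410.8 ± 34.6 (3.13-fold lower, log2 -1.65, SE 0.14, adjusted p = 0.00146). Dimmer Ptch1 probe sets differed by less, at -0.59 (limma adjusted p = 0.044) and -0.43 (0.182, which did not pass). The Gli1 level in Ihh-ablated uteri, at the 27 percentile of all probe sets, was not shown to lie above background, so the size of its fold is uncertain. Each of the 3 Ihh-ablated arrays lay below each control array for both genes, and both calls held without any 1 array.

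Across the Hedgehog target list, 2 of 8 measured genes fell, 0 rose and 6 did not pass, with a median log2 change of -0.21 (-0.12 with median-centred arrays), and 3 fell when adjusted over the list alone. Camera called the list lower (adjusted p = 0.00592), with an adjusted p of 0.457 with an estimated correlation and 0.0184 by fry. Hhip, which binds and sequesters Hedgehog ligands, differed by -0.19 (adjusted p = 0.447). Nr2f2 (COUP-TFII), a stromal nuclear receptor placed downstream of Ihh, differed by -0.24 (adjusted p = 0.138). The list of other Hedgehog pathway components gave 0 calls among 13 genes (median -0.14, adjusted p = 0.569). Genes that neighbour Ihh on chromosome 1 gave 0 calls among 26 (median -0.06, adjusted p = 0.737), and those near Pgr, the locus that carries the Cre, 0 among 9 (median 0.04, adjusted p = 0.315).

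**Figure D1:**
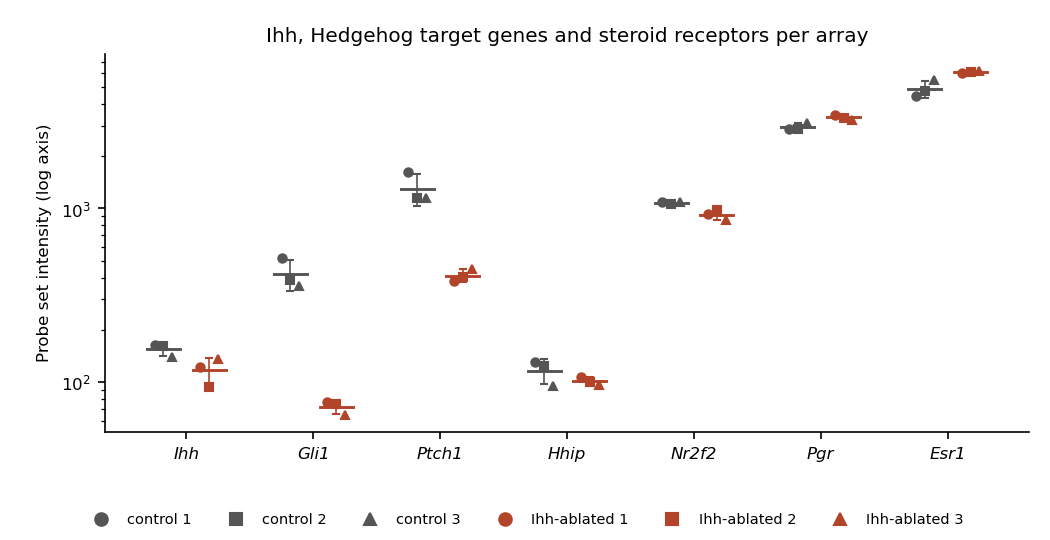
Probe set intensity on a log axis for Ihh, 3 Hedgehog-related genes, Nr2f2, Pgr and Esr1 in each array (points), with the mean (line) and SD (bar) of 3 arrays per genotype. Gli1 and Ptch1 lie lower in all 3 Ihh-ablated arrays, whereas Hhip, Nr2f2, Pgr and Esr1 did not pass the test.

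Over the whole array, 724 of 33777 probe sets and 437 of 15530 genes differed between genotypes at an adjusted p under 0.05 (limma), 199 genes higher and 238 lower in Ihh-ablated uteri. With a fold of at least 1.5, 307 genes were called, 182 of them lower. All 437 genes had groups that did not overlap, as did 32.3% of all genes tested, where chance gives 10%. Of 387 other probe sets of the called genes, 329 had the same direction, and 1 was called in the opposite direction. The count moved with each array left out: 119 genes without control replicate 1, 209 without control replicate 2, 1890 without control replicate 3, 111 without Ihh-ablated replicate 1, 230 without replicate 2 and 174 without replicate 3. Control replicate 3 and Ihh-ablated replicate 2 carried transcripts of other tissues, described further on, and without both, an alternative chosen after seeing the data, 1105 genes were called.

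The largest fall was that of Slc6a2, the noradrenaline transporter, from 919.1 ± 244 to 78.8 ± 21.6 (11.7-fold lower, log2 -3.54, SE 0.23, adjusted p = 0.000492), and 1 of its other 3 probe sets also fell (log2 -0.80, adjusted p = 0.0201), by much less, while the remaining ones read -0.73 (0.0952) and -0.47 (0.164). Dleu7 (log2 -2.55), the secreted angiopoietin-like factor Angptl7 (-2.32) and the matrix protein Vit (-2.03) followed, as did Pclaf, a PCNA-binding replication factor (-2.02), and the monoamine oxidase Maob (-1.86). The proliferation antigen Mki67 fell 3.57-fold from 920.2 ± 37.2 to 262.3 ± 62.3 (log2 -1.84), and Ccnb2 (cyclin B2) by 1.71 on the log2 scale. Vcan, the proteoglycan versican, fell by 1.71, Acta1, the skeletal alpha-actin, by 1.73, and Tac2, which encodes neurokinin B, by 1.76. The largest rise was that of Aspg, an asparaginase, from 238.0 ± 53.8 to 1069 ± 194 (4.52-fold, log2 2.18, SE 0.19, adjusted p = 0.00152). Adamdec1, a metalloprotease (log2 1.96), P2ry14, a receptor for UDP-sugars (1.82), the secreted glycoprotein Olfm4 (1.69), Spink1, a trypsin inhibitor (1.62), and the methyltransferase Inmt (1.61) came next. Inhbb, the beta B subunit of inhibin and activin, rose 2.78-fold from 893.1 ± 260 to 2414 ± 256 (log2 1.48, adjusted p = 0.00845). Ano4 (1.46), Gstm7 (1.44), Pamr1 (1.34), the lipocalin Lcn2 (1.29) and Bex1 (1.28) completed the list of 12 rises. Another Gstm7 probe set read -0.31 (adjusted p = 0.270), another Inhbb probe set 0.52 (adjusted p = 0.0899) and another Pclaf probe set -0.83 (adjusted p = 0.0848). The lower level of several of these genes was near or below that of Gli1 in Ihh-ablated uteri, among them Slc6a2 and Adamdec1 (37.7 in control), and the size of such folds is likewise uncertain. Among these genes, 8 lost the call without at least 1 array. Without control replicate 1 these were Adamdec1 (adjusted p = 0.101), Olfm4 (0.0820), Spink1 (0.0969), Inmt (0.0566), Gstm7 (0.105), Lcn2 (0.104), Bex1 (0.0664) and Tac2 (0.140). Without control replicate 2 they were Adamdec1 (0.0822), Olfm4 (0.0607), Spink1 (0.0902), Gstm7 (0.118), Lcn2 (0.0948) and Tac2 (0.127), and without Ihh-ablated replicate 1 they were Olfm4 (0.0665), Spink1 (0.0849), Gstm7 (0.133), Lcn2 (0.101) and Tac2 (0.119). Spink1 and Tac2 also lost it without Ihh-ablated replicate 2 (0.0581 and 0.0864) and, with Gstm7, without Ihh-ablated replicate 3 (0.0556, 0.155 and 0.160). With the adipocyte marker mean as a covariate, chosen after seeing the data, 11 of these 12 rises lost the call, all but Aspg, as did the falls of Maob, Vcan, Ccnb2 and Tac2. That covariate takes 1 of 4 residual degrees of freedom, and all 437 called genes kept their direction with it. A lost call alone thus does not tie a gene to adipocyte content. Spink1, Gstm7 and Tac2 also lost it after quantile normalization, without the filter on dim probe sets, without an intensity trend and with robust eBayes. Tac2 lost it with median-centred arrays, Lcn2 without a trend, Adamdec1 with a floor of 64 and Gstm7 with the mean of its probe sets.

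**Figure D2:**
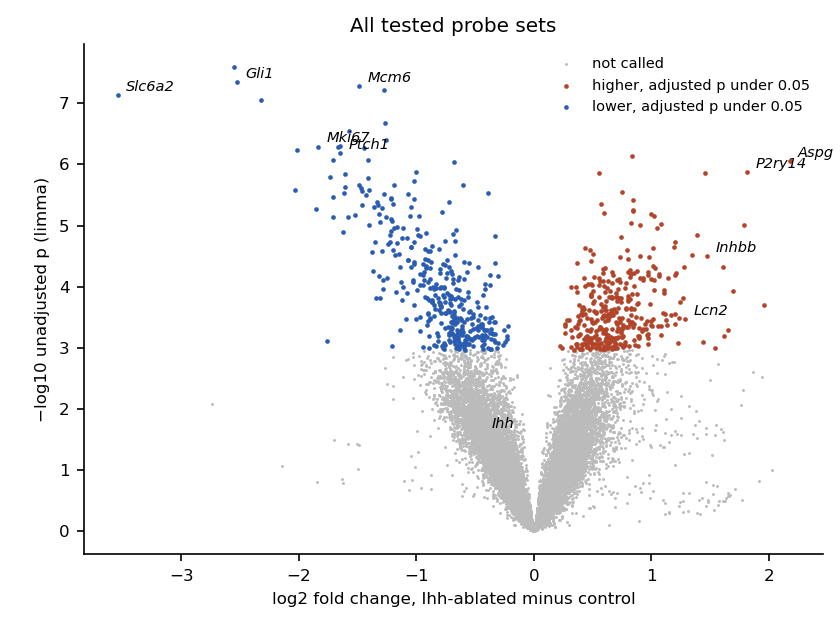
Volcano plot of all 33777 tested probe sets, with the log2 fold change (Ihh-ablated minus control) against -log10 of the unadjusted limma p. Coloured points passed an adjusted p of 0.05, 348 higher and 376 lower, and Slc6a2 stands farthest to the left at -3.54.

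Cell division transcripts were lower in Ihh-ablated uteri. Of 35 measured mitotic cell cycle genes, 28 fell, 0 rose and 7 did not pass (33 fell adjusted over the list alone), with a median log2 change of -1.08. Top2a, the topoisomerase of dividing cells, changed by -1.27, Ccna2 (cyclin A2) by -1.67 and Cdk1, the mitotic kinase, by -1.71 (adjusted p = 0.000997, 0.00139 and 0.00152). Among 30 DNA replication genes, 19 fell, 0 rose and 11 did not pass (23 adjusted over the list alone), with a median of -0.70. Examples are Mcm6 (-1.49) and Mcm5 (-1.58), subunits of the replicative helicase, and Rrm2 (-1.65), the regulated subunit of ribonucleotide reductase. Camera gave adjusted p values of 2.44e-29 and 2.6e-20 for both lists, each 0.457 with an estimated correlation, and fry gave 0.0169 and 0.00918. In each list the 3 Ihh-ablated arrays lay below the 3 control arrays. The number of fallen mitotic genes was 16 without control replicate 1, 17 without Ihh-ablated replicate 1 and 28 without both arrays that carry other-tissue transcripts, and that of replication genes 10 without Ihh-ablated replicate 1. Adipocyte transcripts differed between arrays at the same time, and with their mean as a covariate, chosen after seeing the data, 4 mitotic and 3 replication genes fell, with medians of -1.04 and -0.60.

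**Figure D3:**
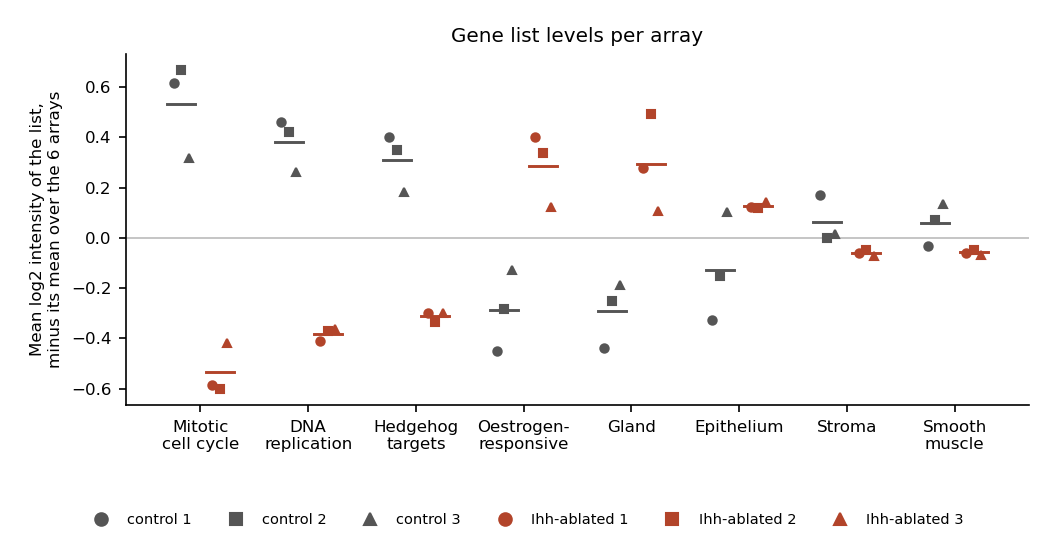
Mean log2 intensity of 8 gene lists in each array, relative to the mean of the list over the 6 arrays, with points for arrays and lines for genotype means. The mitotic list lies between 0.32 and 0.67 in control and between -0.60 and -0.42 in Ihh-ablated arrays, whereas the oestrogen-responsive list lies above 0 in the 3 Ihh-ablated arrays.

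Oestrogen-responsive transcripts were higher in Ihh-ablated uteri. Of 18 measured genes of that list, 6 rose, 0 fell and 12 did not pass (13 rose adjusted over the list alone), with a median log2 change of 0.75. Ltf (lactotransferrin), a classical oestrogen-induced secretory product of the uterine epithelium, rose by 0.98, Greb1 by 0.97, the chemokine Cxcl15 by 0.79 and the water channel Aqp5 by 1.12, and Lcn2 and Ramp3 also passed. Camera gave an adjusted p of 2.38e-07, which was 0.457 with an estimated correlation, and fry gave 0.0938, which did not pass. The number of risen genes was 1 without control replicate 1, 2 without control replicate 2, 11 (beside 1 fall) without control replicate 3 and 1 without Ihh-ablated replicate 1, and 0 with the adipocyte mean as a covariate. With that covariate the median was still 0.59, and camera still called the list. Ltf kept its call without any 1 array, whereas Greb1, Cxcl15 and Aqp5 lost theirs without control replicate 1 (adjusted p = 0.0575, 0.0706 and 0.0575), control replicate 2 (0.0552, 0.0593 and 0.0748) or Ihh-ablated replicate 1 (0.0540, 0.0688 and 0.101), and Aqp5 also without Ihh-ablated replicate 3 (0.0826). Uterine gland markers were also higher: 4 of 10 rose (Gpx3, Cxcl15, Sox9 and Spink1), 0 fell, and the median was 0.64 (camera adjusted p = 9.98e-05, and 0.457 with an estimated correlation). Gland calls fell to 0 without control replicate 1, without control replicate 2 and without Ihh-ablated replicate 1, and to 2 without Ihh-ablated replicate 2. Spink1 is also made by the pancreas, and it was brightest, at 1981, in Ihh-ablated replicate 2. General epithelial markers had a median of 0.25 over 20 genes, with 0 past the test, among them Krt7 at 0.56 (adjusted p = 0.0572). Camera gave 0.000205 for the list (0.570 with an estimated correlation, 0.2395 by fry and 0.133 with the adipocyte covariate). Of these, 9 rose without control replicate 3 (median 0.34) and 8 without both arrays that carry other-tissue transcripts.

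Neither the progesterone receptor nor the oestrogen receptor passed the test. Pgr differed by 0.18 (adjusted p = 0.130) and Esr1 by 0.32 (adjusted p = 0.0547), although another Esr1 probe set rose by 0.48 (adjusted p = 0.00738). Without control replicate 3 both receptors passed (Pgr 0.22, adjusted p = 0.0474, and Esr1 0.41, adjusted p = 0.00339). Esr1 passed in 6 of 20 alternatives and Pgr in 1 of 20. The list of steroid receptors and co-regulators had 1 rise in 12, that of Nrip1 (log2 0.60), and an adjusted p of 0.0337 (0.550 with an estimated correlation). Its call was lost in 8 of 22 alternatives: without control replicate 1 and without Ihh-ablated replicate 3 (highest adjusted p 0.0772), after quantile normalization (0.0591), with median-centred arrays (0.0840), with the lowest 50% left out (0.0565), with the estimated correlation, by fry (0.151) and with the adipocyte covariate (0.133). Nrip1 lost its own without each array but control replicate 3 (0.0503 to 0.109). Progesterone-responsive genes showed no common shift: 2 of 19 fell, Il13ra2 (-1.58) and Acod1 (-1.21), while 17 did not pass, and the median of 0.01, the mean of -0.13 and the camera test differed in sign (adjusted p = 0.967). Adjusted over the list alone, 3 rose and 5 fell. Il13ra2 kept its call without any 1 array and lost it, but not its direction, with the adipocyte covariate (adjusted p = 0.0808). Acod1 passed in 6 of 20 alternatives and lost its call, among others, without control replicate 1 (0.141), control replicate 2 (0.121), Ihh-ablated replicate 2 (0.107) and Ihh-ablated replicate 3 (0.0815). Of 18 decidualization genes on the array 14 were tested, and 0 passed (median -0.07, camera adjusted p = 0.931). The closest was Hand2 at -0.43 (limma adjusted p = 0.0513, and 0.0331 without control replicate 3). All samples are from day -1, so these values do not show whether the genes depend on Ihh later in the decidual response. With adjustment over this list alone, 3 rose and 3 fell. Without control replicate 3, 2 decidualization genes rose and 3 fell, as many as without both arrays that carry other-tissue transcripts. Prostaglandin synthesis and receptor genes had 1 fall in 12, that of Ptger4 (-0.51), with an adjusted p of 0.943 and a median of -0.01 whose sign differed from the test.

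Transcripts of signalling and of the matrix changed in single members. Immediate early genes, which respond within minutes to stimulation or handling, had 3 rises in 17, Jun (0.49), Dusp1 (0.74) and Fos (1.08), a median of 0.28 and an adjusted p of 0.000142 (0.457 with an estimated correlation); the median was 0.17 without Ihh-ablated replicate 1, and the rises numbered 0 without control replicate 1, without Ihh-ablated replicate 1 and without Ihh-ablated replicate 3, and 1 without control replicate 2. EGF family genes had 2 rises in 18, the feedback inhibitors Spry1 (0.64) and Errfi1 (0.32), with an adjusted p of 0.0225 (0.457 with an estimated correlation), lost without control replicate 1 (0.0602) and by fry (0.09997). Collagen and matrix genes moved both ways: Vcan, Col18a1 (-0.81), Col4a1 (-0.37) and Col5a2 fell while Fbln1 (0.55) and Dcn rose, out of 30 (adjusted p = 0.296). Matrix remodelling genes had 3 rises in 20, Plat, Timp3 and Timp2 (adjusted p = 0.169). WNT genes had 2 rises in 25, Rspo1 (0.72) and the WNT target Axin2 (0.68), with an adjusted p of 0.315. BMP and TGF-beta genes had 2 rises, Inhbb and Smad7 (0.94), and 1 fall, Fstl1 (-0.46), in 25 (adjusted p = 0.296). FGF and IGF genes had a rise of Igfbp5 (0.57) and a fall of Igfbp4 (-0.25) in 18 (adjusted p = 0.418). Angiogenesis factors had 2 rises in 18, Vegfa (0.75) and Adm (0.62), with an adjusted p of 0.113. Water and ion transport had 1 rise in 14, that of Aqp5 (adjusted p = 0.126). Glycolysis genes had 2 falls in 16, Pkm and Tpi1 (adjusted p = 0.304), and 0 of 17 cholesterol synthesis genes passed (adjusted p = 0.117). The cholesterol list was called with the lowest 50% left out, without control replicate 3 (where 2 genes fell) and without Ihh-ablated replicate 1. Respiratory chain genes had 1 fall in 18, that of Cox6c (-0.30), with an adjusted p of 0.0716 and 0.0310 by fry, and 0 of 17 ribosomal protein genes passed (median 0.01, adjusted p = 0.296). Of the 95 called genes of all lists, 35 kept the call without any 1 array, Inhbb, Vcan and Col18a1 among them, and 39 did without control replicate 1, 55 without control replicate 2, 95 without control replicate 3, 37 without Ihh-ablated replicate 1, 59 without replicate 2 and 58 without replicate 3. The call was kept by 85 after quantile normalization, 73 with median-centred arrays and 11 with the adipocyte covariate.

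Markers of other cell types were compared in the same way. Endometrial stroma markers had a median of -0.11 over 14 genes, with falls of Thy1 (-1.44, a call kept without any 1 array) and Vim (-0.37) and rises of Rspo1 and Dcn (adjusted p = 0.368). Smooth muscle markers had a median of -0.08 over 16, with falls of Hspb6 (-0.78) and Actg2 (-0.25), and a camera adjusted p of 0.149. That list was called after quantile normalization and with the adipocyte covariate. Endothelial markers had 1 fall in 16, that of Cdh5 (adjusted p = 0.315). Macrophage markers (median 0.19 over 15, adjusted p = 0.00177, and 0.550 with an estimated correlation) and interferon-stimulated genes (median 0.25 over 18, adjusted p = 0.0015, and 0.570) were called higher as lists, with 0 genes past the test in either. Ihh-ablated replicate 3 stood apart in the interferon list, at 0.42 relative to the 6-array mean against -0.02 and 0.01 in the other Ihh-ablated arrays, and without it the median was 0.12 (adjusted p = 0.0380). Antigen presentation genes (13, adjusted p = 0.0337, and 0.609) lost their call in 10 of 22 alternatives. Among these were the fits without control replicate 1, without control replicate 2 and without Ihh-ablated replicate 3 (highest 0.128), where their median of 0.19 became 0.10. The others, beside the estimated correlation, were quantile normalization (0.0545), median-centred arrays (0.0600), array weights (0.0940), the fit without probe sets of shared sequence (0.225), fry (0.350) and the adipocyte covariate (0.292). Mesothelial markers (7, 1 rise of Rspo1, adjusted p = 0.0357, and 0.457) lost it in 9 alternatives: without control replicate 3 and without Ihh-ablated replicate 1 or replicate 2 (highest 0.0619), without both arrays that carry other-tissue transcripts (0.0906), with median-centred arrays (0.0600), with the lowest 50% left out (0.122), without probe sets of shared sequence (0.209), by fry (0.141) and with the estimated correlation. Their median of 0.29 ranged from 0.19 without control replicate 2 or Ihh-ablated replicate 1 to 0.48 without Ihh-ablated replicate 3. Ciliated and oviduct markers (7, 1 fall of Tppp3, adjusted p = 0.0357, and 0.532) lost their call in 7 alternatives: without control replicate 1 (0.192), after quantile normalization (0.0574), without the filter on dim probe sets (0.0511), with the replicate block (0.0614), by fry (0.0938), with the adipocyte covariate (0.292) and with the estimated correlation. Lists for NK and T cells (12, adjusted p = 0.149), B and plasma cells (6, 0.382), neutrophils and eosinophils (7, 0.205), mast cells (8, 0.716), red cells (4, 0.655), ovary (6, 0.528) and nerve and glia (6, 0.430) gave 0 calls of genes each.

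Transcripts of tissues outside the uterus stood out in single arrays. In Ihh-ablated replicate 2, 25 genes were at least 4-fold brighter than in every other array, among them the pancreatic enzymes Cpa1, Pnliprp1 and Cela3b, chosen after their values were seen. In control replicate 3, 10 genes were, led by the fast-muscle proteins Myl1 and Mylpf, likewise chosen after seeing them, and in the other 4 arrays 0 were. Skeletal muscle markers had a median log2 difference of -1.20 between genotypes over 9 genes (adjusted p = 0.00184, and 0.589 with an estimated correlation), with 1 fall, that of Acta1. Without control replicate 3 the median was -0.21, 4 of the 9 genes fell and the list stayed called (adjusted p = 0.0109), and relative to the 6-array mean it read -0.20 and -0.05 in the other control arrays against -0.63, -0.80 and -0.59 in Ihh-ablated uteri. Adipocyte markers had a median of 1.21 over 10 genes, with 0 past the test over all genes and 6 adjusted over the list alone, and an adjusted p of 0.00514 (0.589 with an estimated correlation). Relative to the 6-array mean, the adipocyte list read -1.39, -0.24 and 0.22 in control and 0.01, 0.40 and 1.01 in Ihh-ablated uteri, so the genotypes overlapped. Without control replicate 3, 6 adipocyte genes rose with a median of 1.67, and without control replicate 1 the median was 0.66 with 0 rises. Called members of other lists moved with the arrays too. Without control replicate 3, 37 of 43 lists had at least 1, against 25 with all arrays, and 26 lists had over 1.5 times as many. Over all lists, rises went from 32 to 86 and falls from 68 to 106 in that fit. Genes called over the whole array went from 437 to 1890 at the same time, so the gain was not particular to the lists. With any other single array left out, 9 to 16 lists had called members. Of all 43 lists, 16 were called by camera, 11 higher and 5 lower, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 4 by fry.

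**Figure D4:**
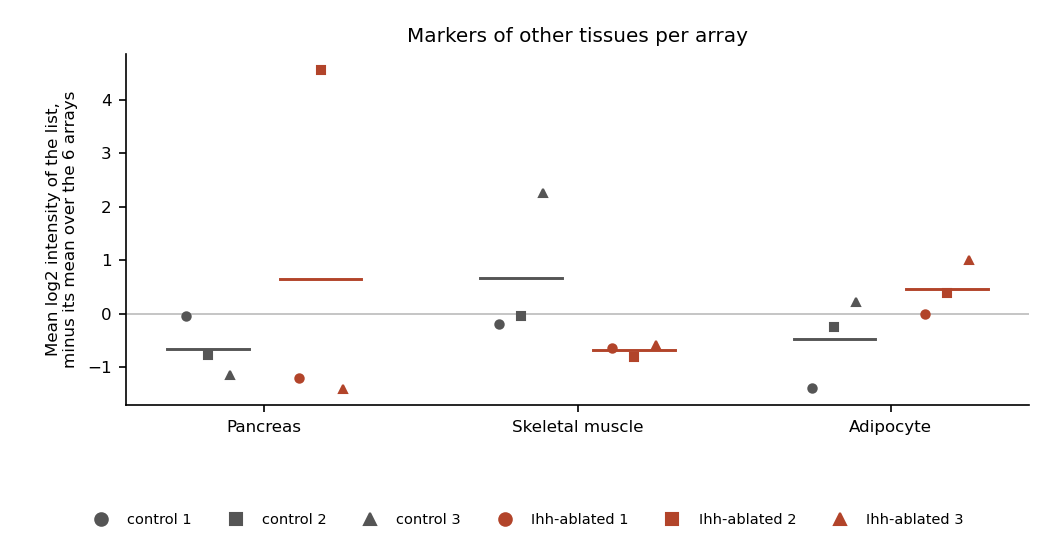
Mean log2 intensity of pancreas, skeletal muscle and adipocyte markers in each array, relative to the mean of the list over the 6 arrays, with points for arrays and lines for genotype means. Pancreas markers reach 4.56 in Ihh-ablated replicate 2, skeletal muscle markers 2.26 in control replicate 3, and adipocyte markers range from -1.39 to 1.01.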

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

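The fit without both arrays that carry other-tissue transcripts and the one with an adipocyte covariate were chosen after seeing the data, and the other alternatives were planned. All 437 genes kept their direction in every alternative, except that 436 of 437 did with the mean of probe sets and 431 of 432 without probe sets of shared sequence, while 393 remained tested with 50% of probe sets left out. Leaving out arrays or weighting them could not reverse a direction, because the groups of all 437 genes did not overlap. The other filters, variance models, thresholds and set tests, and the replicate block, leave the log2 difference of a probe set as it was. Those alternatives therefore do not test the direction. The count of genes moved more: 266 with median-centred arrays, 226 without an intensity trend, 782 with array weights, 1022 at an adjusted p of 0.10, 1105 without both arrays and 23 with the adipocyte covariate, which takes 1 of 4 residual degrees of freedom, and 111 to 1890 with 1 array left out. Called probe sets numbered 374 without a trend, 1411 with array weights, 1852 at 0.10, 1915 without both arrays, 28 with the covariate and 156 to 3569 with 1 array left out. The cause of these shifts was not tested. Higher calls were 45.5% of called genes, 37.1% after quantile normalization, 51.5% after median centring, 31.9% without a trend, 8.7% with the covariate, and 27.7% without control replicate 1, 29.2% without control replicate 2, 37.8% without control replicate 3, 27.9% without Ihh-ablated replicate 1, 44.8% without replicate 2 and 34.5% without replicate 3. Whether replicate numbers pair the samples cannot be told from so few arrays. Same-numbered deviations correlated at -0.152, -0.043 and 0.249, and the others at -0.237 to 0.319. The replicate block raised the calls to 1562 probe sets and 922 genes, and gave 15 lists. It gave rises of 4 epithelial and 7 adipocyte markers, an adjusted p of 0.00757 for Hedgehog targets (camera) and 0.172 for Ihh (limma). With an estimated correlation 0 lists were called, and Hedgehog targets (-0.21) had an adjusted p of 0.457, against 0.0025 to 0.0271 in the other alternatives, and fry called 4 lists. Ihh passed in 0 of 20 alternatives (adjusted p 0.0993 to 0.578), and Gli1 and Ptch1 in 20 of 20. A floor at 1 moved nothing, because values at the floor were in filtered probe sets, and a batch of scan dates was not run. Over 919 comparisons of the other lists with an alternative, 823 stayed on their side of the threshold in the same direction, 57 lost a call, 15 gained one, 24 changed sign while uncalled and 0 reversed; over 3648 of the other named genes these were 3162, 322, 156, 8 and 0. For lists, the alternatives without an intensity trend and with robust eBayes could not differ from the main fit, because the list tests do not use those settings. They and the floor at 1 are counted among the 823 and among the alternatives given for each list, and add no evidence of stability there. Signal over background could not be judged, for Ihh or for any other gene.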

Other observations

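The gene groups of the next paragraph and all tests of explanations in this part, the other splits of the arrays and the thresholds included, were written down after results had been seen.

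Of 15 measured genes for enzymes, carriers and receptors of retinoids, 2 rose, 1 fell and 12 did not pass: Aldh1a2, which makes retinoic acid in stroma, rose by 0.90 on the log2 scale (adjusted p = 0.0043), the alcohol dehydrogenase Adh1 rose by 0.73 (adjusted p = 0.0134), and Crabp1, a cytosolic retinoic acid binding protein, fell by 0.98 (adjusted p = 0.00537). Among 14 calcium-binding S100 proteins, annexins and galectins, 4 fell and 0 rose, namely S100a6 (-0.68), S100a10 (-0.61), its partner Anxa2 (-0.48) and Lgals1 (-0.33), all bright in every array. Of 6 genes of monoamine transport and breakdown, Slc6a2 and Maob fell, and Maoa differed by -0.43 (adjusted p = 0.085). These genes were chosen after their values were seen, so their counts are descriptions and not tests of a group.

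The genotypes could be compared with the other splits of the 6 arrays into groups of 3. Counting the real split, 1 of 10 splits gave 724 probe sets or more, 437 genes or more and 16 lists or more. The highest other split gave 0 probe sets, 0 genes and 10 lists. Each other split mixes both genotypes within a group, so a genotype difference adds to its residual spread and lowers its calls of genes. Its counts therefore do not show what arrays without a genotype difference would give. With 10 splits the share is never under 0.05. Other splits called 4 to 10 lists by camera with its preset correlation.

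Genes of other tissues were high in single arrays. Of 6 pancreas markers that had not been seen when the marker list was written, 6 lay at least 4-fold above every other array in Ihh-ablated replicate 2, and the pancreas markers were 61.6-fold above the median of the other arrays there (Reg1 and Pnliprp1 by 5.43 and 5.34 log2 above the next array). The remaining Ihh-ablated arrays lay -0.657 from the controls on the log2 scale, which argues against Ihh ablation as the source. Likewise 5 of 9 skeletal muscle markers lay at least 4-fold above every other array in control replicate 3, and the Ihh-ablated arrays lay a median of -0.211 from the other controls, with a lower quartile of -0.757, 4 of 9 markers lower and the list still called (camera adjusted p = 0.0109), so a genotype difference in some muscle transcripts stays open beside it. Over all arrays that list had an adjusted p of 0.589 with an estimated correlation and 0.2395 by fry. Pancreatic and muscle tissue carried into these samples at dissection is a candidate source of the peaks in both arrays, as a hypothesis.

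Cell cycle and DNA replication genes were lower in Ihh-ablated uteri, with a median of -0.942 over both lists. A general loss of stromal cells would have lowered stroma markers alike, but these changed by a median of -0.108, and the difference from the cycle genes had a lower bound of 0.671. Members of the stroma list moved both ways, with 2 called higher and 2 lower. Their median therefore cannot decide on a loss of some kinds of stromal cells. Dilution by tissue outside the uterus would have lowered smooth muscle markers, which changed by -0.077 (lower bound of the difference 0.716). Both bounds measure the spread over genes, which are not independent replicates, and not the spread between arrays. Another scaling moved the median to at most -0.851. A lower rate of division in cells that remained may account for the pattern, as a hypothesis, but a change in which cells divide was not tested, and the adipocyte covariate left the median at -0.881 while few genes stayed called.

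Oestrogen-responsive genes were higher in Ihh-ablated uteri. A larger share of epithelium cannot be told apart from a rise within epithelial cells: epithelial markers changed by a median of 0.25, and the difference between the lists was 0.497 with 95% bounds of -0.072 to 0.718, which include 0. The bounds come from 10000 bootstrap draws and measure the spread over genes. Genes are not independent replicates, so the bounds do not measure the spread between arrays. Pancreatic tissue in 1 sample is argued against, because the list kept a median of 0.693 without that array (camera adjusted p = 5.2e-07 with the preset correlation; over all 6 arrays the list had 0.457 with an estimated correlation and 0.0938 by fry). A stronger oestrogen response after loss of Ihh may be a candidate explanation. The comparison with epithelial markers could not separate it from a larger share of epithelium. Nor can a stronger oestrogen response be told apart from an effect of the Cre at the Pgr locus.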
